A study of Zea mays with 6 samples.

How the data were processed

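Gene expression was measured by mRNA sequencing in 6 libraries of maize (Zea mays) leaf tissue, 3 from seedlings of the inbred line Zheng58 (called wild type here) and 3 from seedlings labelled apl in the Zheng58 background (called the apl mutant). Per the labels' protocols, leaves were taken 10 days after germination from greenhouse-grown plants, total RNA was extracted with a Takara reagent, and libraries were made with an Illumina TruSeq kit and read on a NovaSeq instrument. The labels do not say which locus is mutated in apl, how the mutant was made, or whether the libraries of a group came from separate plants or pools of plants. The p-values therefore measure the spread between these libraries, which may be partly technical.

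The values analysed are relative transcript abundances in TPM, deposited by the authors as 1 table with 1 column per library and 44303 gene identifiers. Per the submitters' processing notes, Trimmomatic 0.36, HISAT2, RSEM and DESeq2 were used. Those notes give no role or order for the tools, and the genome build and annotation version are not given in the sources used here. TPM is normalized for transcript length and for each library's total, so it carries no sequencing depth: the depth of each library is unknown and no counting interval or detection floor is given. The listed genes summed to between 930426 and 959685 TPM per library, so 4.03% to 6.96% of each library's full TPM sum was assigned to features outside the table. TPM is a share of a whole, and a large change in abundant transcripts moves the value of every other gene. RSEM estimates can also be exactly 0 when no read is assigned, so a gene at 0 is described only as listed at 0.

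The table holds identifiers without gene names. None of them matched the names, synonyms or tags in the maize gene table used for names (49888 genes, assembly Zm-B73-REFERENCE-NAM-5.0), and the count of matches was 0. No gene symbol, function or coordinate is therefore reported. The 46 gene lists fixed before the data were examined (photosynthesis, defence, hormone, sugar, vascular and other lists, with markers of leaf cell types) relied on names, so 0 of them could be applied, and the planned tests of gene lists were not run. Identifiers are printed for 4 genes only.

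Values were transformed as log2(TPM + 1), and genes with a mean of at least 1 TPM over all 6 libraries were tested (20411 genes). A linear model with genotype as its only term was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. A fold change is on the log2(TPM + 1) scale, apl mutant minus wild type, which understates the change of genes at low TPM. Library-level measures were compared with two-sided exact permutation tests in SciPy 1.17.1, where 3 libraries against 3 cannot give a p below 0.1. The fit, the filter, the threshold, the rule for named genes and the alternatives for the fit, except the 2 rescalings without mutant replicate 2, were set before the data were examined. The rule names, among genes past the threshold with non-overlapping groups and a mean of at least 5 TPM in the higher group, the 2 with the largest positive and the 2 with the largest negative change. The other parts of the rule needed gene names. One part called for any gene named apl, and this could not be looked up.

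Both groups carry replicate numbers 1 to 3, and the labels do not say that a number marks a shared day or batch. No pair of libraries with identical values was found: between 0.372% and 1.14% of tested genes had the same TPM in any pair. The labels give no sequencing batch or date, so no analysis within batches was made. The fit was tested on simulated data with 200 changed genes among 20411, with the gene means of the 6 libraries and the spread from the empirical Bayes step. It recovered 38% of genes changed by 1 log2 unit, 80% by 2, 94% by 3 and 98% by 4, with 12 false calls among 167. With the spread found without apl mutant replicate 2 (20511 genes), it recovered 68%, 94%, 98% and 100%, with 14 false calls among 194. The simulated spread was equal in both groups and independent between genes. These rates therefore do not cover data in which 1 library is displaced over many genes at once.

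The alternatives were pseudocounts of 0.1 and 5 TPM, no filter and a mean filter of 5 TPM, median-of-ratios rescaling, quantile normalization, no trend, robust hyperparameters, array weights, a replicate block, an added 2-fold limit, and leaving out each library in turn. Chosen after the data were seen were the count of all-or-none genes (at least 5 TPM in every library of 1 group and at most 0.1 TPM in every library of the other), the relative position of mutant replicate 2, the 2 rescalings without mutant replicate 2, and the analysis of identifier order. The relative position is 0 at the wild type mean and 1 at the mean of mutant replicates 1 and 3, on the log2(TPM + 1) scale.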

Results

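The transcriptomes of apl mutant leaves and of leaves of the background line Zheng58 were profiled in triplicate, giving 6 maize libraries from second leaves of 10-day seedlings. Zheng58 is an inbred maize line, and the comparison asks which transcripts differ between the mutant and this background. Expression was given in TPM, so the number of reads behind each library is unknown. The wild type libraries had 27184, 27006 and 26464 genes above 0, and the apl mutant libraries 28391, 26742 and 28149, in the order of their replicate numbers. The group means were 26885 ± 375 genes in wild type and 27761 ± 890 in the mutant (SD, n = 3 each). Their difference had a two-sided p of 0.3 in an exact permutation test, where 3 against 3 cannot go below 0.1. Mutant replicate 2 alone among the mutant libraries lay within the wild type range. The 10 most abundant genes of each library took 10.3% ± 0.35 of the listed TPM in wild type and 9.65% ± 1.89 in the mutant (SD, n = 3 each, exact permutation p = 0.6).

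The 3 wild type libraries resembled each other closely, and the 3 mutant libraries did not. Across the 20411 tested genes, Pearson correlations of log2(TPM + 1) between wild type libraries were 0.979 to 0.982. Mutant replicates 1 and 3 correlated with each other at 0.952 and with the wild type libraries at 0.887 to 0.912. Mutant replicate 2 correlated with the wild type libraries at 0.950 to 0.956, and with mutant replicates 1 and 3 at only 0.885 and 0.900. These correlations are across genes, which are not independent replicates. The first principal component held 59.1% of the variance. On it the wild type libraries scored -36.1, -40.3 and -37.8, mutant replicate 2 scored -33.5, and mutant replicates 1 and 3 scored 80.6 and 67.0. The second component (17.9%) set mutant replicate 2 at -61.7 apart from the other libraries, which lay between -0.593 and 21.6.

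**Figure D1:**
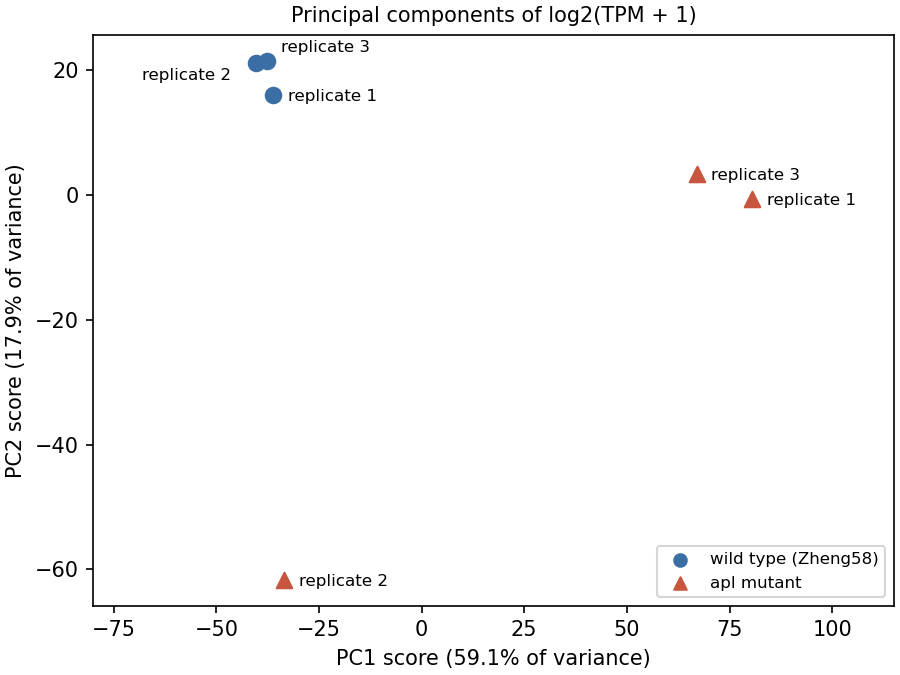
Scores of the 6 libraries on the first 2 principal components of log2(TPM + 1) over 20411 genes (no unit, share of variance on each axis), with circles for wild type and triangles for the apl mutant. On the horizontal axis apl mutant replicate 2, at -33.5, lies beside the wild type libraries, and on the vertical axis it lies apart from all others at -61.7.

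Between the apl mutant and wild type, 287 of the 20411 tested genes changed (1.41%, limma, adjusted p under 0.05), 135 of them higher and 152 lower in the mutant. The number rested on mutant replicate 2. Without it, 7140 of 20511 tested genes changed (34.8%), 4141 higher and 2999 lower, and 286 of the 287 genes were among them, each in the same direction. That split by direction depended on the scaling: it was 3611 higher and 3550 lower after median-of-ratios rescaling, and 3043 higher and 4034 lower after quantile normalization. Leaving out mutant replicate 1 gave 132 genes and leaving out mutant replicate 3 gave 156. Leaving out wild type replicate 1, 2 or 3 gave 85, 84 or 93 genes. Over all 6 libraries the median log2 change of the tested genes was 0.04, and 3933 genes had an unadjusted p under 0.05.

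Many of the 287 changes were large. At least a 2-fold change on the log2(TPM + 1) scale was seen for 108 of the higher and 125 of the lower genes. A change of at least 3 log2 units was seen for 21 higher and 12 lower genes. In all 287 genes the 3 mutant values lay entirely above or entirely below the 3 wild type values. With 3 libraries per group the threshold largely requires such a separation. It was also the case for 5571 of all tested genes (27.3%), where chance gives 10% if all 6 libraries are interchangeable. Mutant replicates 1 and 3 lay together away from the other libraries, so the excess over 10% does not show a change shared by all 3 mutant libraries. Each of the 287 genes thus has mutant replicate 2 on the same side as mutant replicates 1 and 3. By abundance, 48 of the higher genes had a mean of 1 to under 5 TPM, 58 had 5 to under 20, 23 had 20 to under 100, and 6 had 100 TPM or more. The lower genes numbered 42, 44, 51 and 15 in these same classes, and all tested genes 6885, 7353, 4852 and 1321.

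Among the changed genes, the largest fall on the log2(TPM + 1) scale was that of Zm00001eb145820. It stood at 91.2 ± 6.75 TPM in wild type and 0.297 ± 0.086 TPM in the mutant (SD, n = 3 each), a log2 change of -6.15 ± 0.11 (SE, limma adjusted p = 3.21e-05). Zm00001eb056030 fell from 110.4 ± 3.92 to 2.37 ± 0.246 TPM (SD, n = 3 each), a log2 change of -5.05 ± 0.10 (SE, limma adjusted p = 3.33e-05). The gene with the largest rise, Zm00001eb307210, stood at 0.323 ± 0.484 TPM in wild type and 59.1 ± 11.8 TPM in the mutant (SD, n = 3 each). Its log2 change was 5.55 ± 0.28 (SE, limma adjusted p = 0.00127). Zm00001eb199610 rose from 0.03 ± 0.026 to 17.2 ± 4.18 TPM (SD, n = 3 each), a log2 change of 4.11 ± 0.20 (SE, limma adjusted p = 0.00127). Mutant replicate 2 had 0.28, 2.53, 47.2 and 20.6 TPM for Zm00001eb145820, Zm00001eb056030, Zm00001eb307210 and Zm00001eb199610, and its agreement with the other mutant libraries was a condition of the rule that named these genes. What these genes encode is not reported here, because their identifiers were not paired with names.

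**Figure D2:**
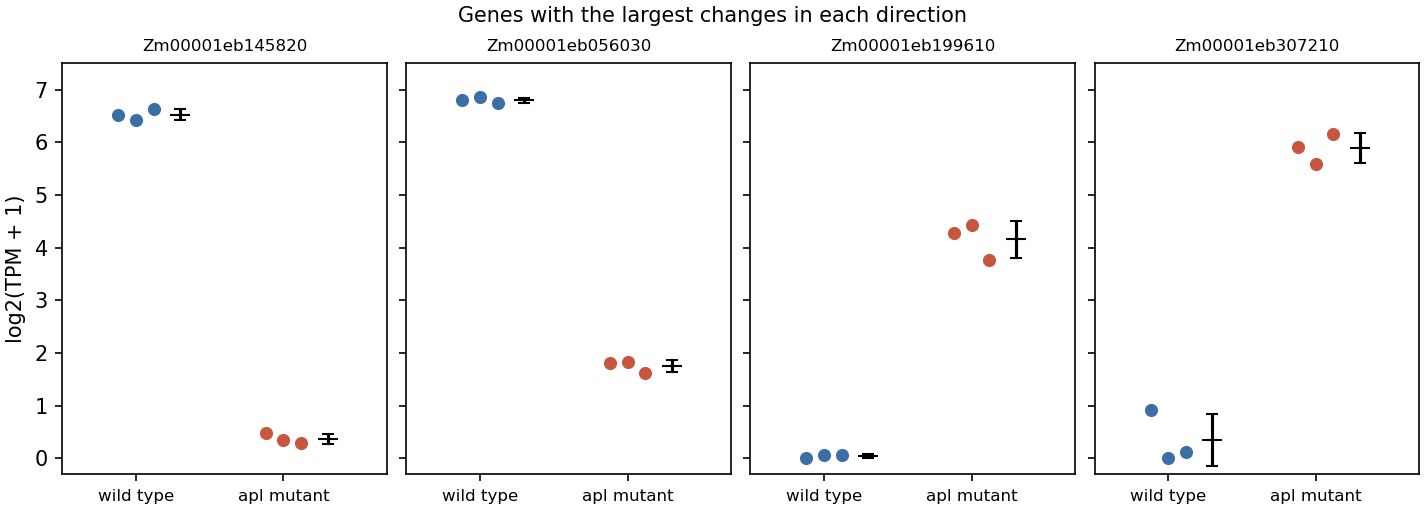
Expression of the 2 genes with the largest fall and the 2 with the largest rise, as log2(TPM + 1) on the vertical axis, with 1 point per library and the group mean with its SD beside the points (n = 3 per group). The groups do not overlap in any of the 4 genes, which the rule for choosing them required.

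Some genes had clear values in every library of 1 group and values at or near 0 TPM in every library of the other. In one direction, 9 genes had at least 5 TPM in every wild type library and at most 0.1 TPM in every mutant library, and 7 of them were listed at 0 in all 3 mutant libraries. Their wild type means ran from 6.45 to 24.1 TPM. Another 11 genes had at least 5 TPM in every mutant library and at most 0.1 TPM in every wild type library, and 10 of these were listed at 0 in all 3 wild type libraries. Their mutant means ran from 6.68 to 17.2 TPM. All 20 genes were among the 287, which so wide a gap between the groups made likely. These limits were chosen after the data were seen, and the numbers depend on them. Presence at 2 TPM gave 16 genes low in the mutant and 27 low in wild type, and presence at 10 TPM gave 2 and 1. Without mutant replicate 2 the numbers were 9 and 17.

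In the fit without mutant replicate 2, which rests on 2 mutant libraries, changed genes at 20 TPM or more were more often lower than higher under each scaling, and those under 20 TPM were more often higher, except after quantile normalization. The classes use the mean over all 6 libraries, and 62 of the 7140 genes, with a mean under 1 TPM, are in none of them. Of the changed genes with a mean of 1 to under 5 TPM, 1445 were higher and 361 lower in mutant replicates 1 and 3. From 5 to under 20 TPM these numbers were 1453 and 914. From 20 to under 100 TPM, 923 were higher and 1165 lower, and at 100 TPM or more 268 were higher and 549 lower. After quantile normalization the 4 classes held 766, 1061, 866 and 320 higher genes and 852, 1438, 1237 and 486 lower genes. In the fit of the values as deposited, without rescaling, at least a 2-fold change was seen for 1845 higher and 754 lower genes. Among the 10 genes with the highest mean TPM over the 6 libraries, 5 changed in this fit and 0 changed with all 6 libraries. The most abundant gene had 21156, 29175 and 21510 TPM in the wild type libraries. In mutant replicates 1 and 3 it had 5497 and 7579 TPM, a log2 change of -1.88 (limma adjusted p = 0.00266 without replicate 2), and in mutant replicate 2 it had 32654 TPM. The gene ranked 8 by mean TPM had 8269, 9212 and 7737 TPM in wild type, 2792 and 3858 in mutant replicates 1 and 3, and 9496 in mutant replicate 2. Of the 5 genes, the one ranked 6 alone was higher in mutant replicates 1 and 3. It had 6663, 5692 and 6946 TPM in wild type, 10706 and 9390 in mutant replicates 1 and 3, and 7929 in mutant replicate 2. Its log2 change was 0.645 (limma adjusted p = 0.0124 without replicate 2).

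Over the 7140 genes that changed without it, mutant replicate 2 had a median relative position of 0.072 between the wild type mean (0) and the mean of the other mutant libraries (1), with quartiles of -0.188 and 0.421. It lay nearer to the wild type mean in 5644 of these genes (79.0%). In 3197 genes (44.8%) it lay beyond the wild type range in the direction of the other mutant libraries, and in 2040 (28.6%) beyond it in the opposite direction. Of the 159 genes that changed by at least 3 log2 units without it, 137 higher and 22 lower, replicate 2 lay nearer to the wild type mean in 121, 112 of the higher and 9 of the lower genes.

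**Figure D3:**
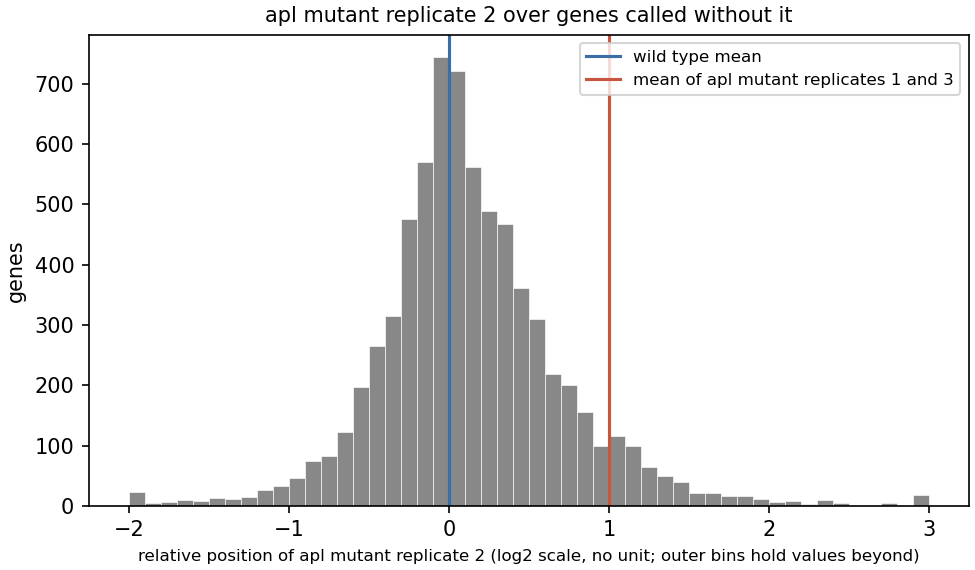
Number of genes (vertical axis) by the relative position of apl mutant replicate 2 (horizontal axis, no unit) over the 7140 genes that changed without it, in bins of log2(TPM + 1) differences where the blue line at 0 is the wild type mean and the red line at 1 the mean of mutant replicates 1 and 3. The outer bins also hold values beyond -2 and 3, the median is 0.072, and 5644 genes lie below the midpoint.

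The 287 changed genes were spread unevenly over the table, whose identifiers run in numerical order. Among 178 windows of 250 consecutive identifiers, 70 held no changed gene, and 17 windows with 5 or more held 134 of the 287. The fullest window, from position 27251 to 27500, held 17 changed genes among 125 tested, 15 higher and 2 lower. The next held 12 (positions 33501 to 33750, 5 higher and 7 lower) and 11 (positions 10751 to 11000, 6 higher and 5 lower). Positions are places in the identifier order, not coordinates. Any reading of nearness as neighbouring genes or chromosome segments assumes that identifiers were numbered along chromosomes, which was not checked.

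**Figure D4:**
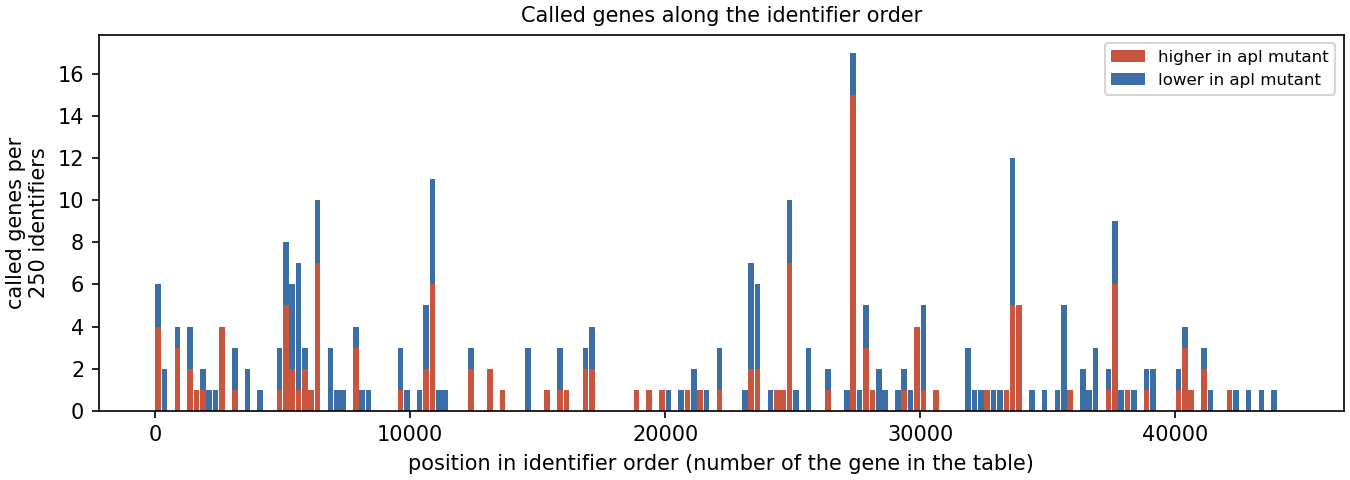
Changed genes per window of 250 consecutive identifiers (vertical axis, number of genes) along the order of the 44303 identifiers (horizontal axis, place in the table), with genes higher in the apl mutant in red and lower ones in blue, stacked. The fullest of the 178 windows holds 17 changed genes, and 70 windows hold none.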

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

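The alternatives for the fit were set before the data were examined, except the 2 rescalings without mutant replicate 2. Those 2, and the alternatives for all-or-none genes and identifier order, were set after. The directions of the 4 named genes and their side of the threshold were the same in all 64 combinations of gene and alternative (limma adjusted p from 4.41e-06 to 0.0333). These genes were chosen from the same libraries for large changes past the threshold, so this agreement was largely fixed by the choice. The total of 287 changed genes stayed within 1.5 times under both pseudocounts, no filter, a mean filter of 5 TPM, both rescalings, no trend, robust hyperparameters and a 2-fold limit (200 to 307). The filter of 5 TPM tests only 13526 genes, and 89 of its calls were higher in the mutant. Without mutant replicate 2, median-of-ratios rescaling gave 7161 changed genes (3611 higher, 3550 lower) and quantile normalization 7077 (3043 higher, 4034 lower), the latter with a median change of all genes of -0.07 against 0.08 as deposited. Array weights gave mutant replicate 2 a weight of 0.152, and 5592 genes changed, 3142 higher and 2450 lower. Leaving out each library in turn gave totals from 84 to 7140, with 48 to 4141 higher and 36 to 2999 lower. The highest values are those without mutant replicate 2 and the lowest those without wild type replicate 2. With a replicate block 25 genes changed, 14 higher and 11 lower, 24 of them among the 287. No pairing by the shared numbers was seen: deviations from the group means correlated at -0.04, 0.05 and -0.02 for numbers 1, 2 and 3. Of the wild type libraries, replicate 2 alone correlated best with its own number. With 3 libraries per group and mutant replicate 2 far from the other mutant libraries, a modest shared effect could be missed. The block also takes residual degrees of freedom from the fit. Without a replicate, all-or-none genes present in the mutant numbered 12 to 17 and those absent from it 9 to 12, against 11 and 9. Presence at 2 TPM gave 27 and 16, and presence at 10 TPM gave 1 and 2. The number of changed genes with another nearby was 104 within 10 identifiers and 218 within 100, where it no longer exceeded random draws (permutation p = 0.164). With all 6 libraries, rescaling moved the median change of all genes by less than 0.1 log2. Tests of gene lists were not run because 0 identifiers matched a name. The unknown depth leaves the counting error of low TPM values open.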

Other observations

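The tests on mutant replicate 2, the comparison with draws from all tested genes, the count with runs taken once, Fisher's exact test and the counts over other splits were chosen after the results were seen. The tests against the genes that changed without replicate 2, of consecutive pairs and of all-or-none genes near other changed genes had their expected outcomes set before their own results were seen, though after the data had been examined.

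Mutant replicate 2 also had expression of its own. In 351 genes it lay at least 2-fold outside the range of the other 5 libraries on the log2(TPM + 1) scale, below them in 269 genes and above them in 82. Mutant replicates 1 and 3 had 428 and 291 such genes, with 375 and 255 of them above, and the wild type libraries had 37 to 48.

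Of the 7140 genes that changed without it, mutant replicate 2 lay nearer to the wild type mean in 5644. It lay beyond the wild type range in 3197 on the side of the other mutant libraries and in 2040 on the opposite side. How many would lie beyond that range by chance was not tested. Of the 159 genes that changed by at least 3 log2 units without it, mutant replicate 2 lay nearer to the wild type mean in 121. A wild type library under the mutant label is argued against: 22 of the 26 all-or-none genes defined without replicate 2 were in the mutant state in it, 9 of 9 absent genes at no more than 0.1 TPM and 13 of 17 present genes at 1 TPM or more (11 at 5 TPM or more). Wild type RNA mixed into the sample would restore the 9 absent genes, whose highest level in replicate 2 was 0.706% of the wild type mean, and a library-wide scaling difference would leave ranks alone, yet the lowest Spearman correlation of replicate 2 with a wild type library was 0.940, against at most 0.884 with another mutant library. Still open, and untested because the labels record none of them, are a difference in harvest, growth or handling, and the hypothesis that replicate 2 came from a plant of the mutant stock that may not have carried or shown the apl condition, while mutant replicates 1 and 3 did. In that case the 287 genes, the 4 named genes and the 20 all-or-none genes, which all need replicate 2 on the mutant side, may mark differences of the stock rather than of apl, which only genotyping the plants behind each library would test. If harvest, growth or handling differed instead, the 7140 genes that changed without replicate 2 may mark that difference rather than apl.

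Changed genes lay near each other in identifier order: of the 287, 147 (51.2%) had another within 25 identifiers, against a mean of 81.6 and a maximum of 121 in 10000 draws from the tested genes (permutation p = 0.0001, the smallest the draws can give). Neighbours that respond together stay open. Draws from the 7140 genes that changed without replicate 2 gave a mean of 83.1 (permutation p = 0.0001, again the smallest). That was the outcome set beforehand against this explanation, but so sparse a draw separates neighbours and decides nothing. In the fullest window 52.8% of tested genes changed without replicate 2, against 34.8% of all. That window was picked for its changed genes, and 286 of the 287 also changed without replicate 2, so its share was raised in advance. The windows with 12 and 11 changed genes had 44.0% and 35.5%. Reads shared between gene copies stay open as part of it. Of 26 pairs at consecutive identifiers, 7 went in opposite directions, fewer than the bound set beforehand for shared reads. Sharing can move copies either way, however, so that bound was wrong and the count decides nothing. Copies at consecutive identifiers are not the whole source: with each such run counted once, 114 genes had another within 25, against a mean of 77.96 in the draws (permutation p = 0.0002). One hypothesis is that the mutant stock may carry chromosome segments of a background other than Zheng58, and its tests were not decisive. In them 7 of the 20 all-or-none genes had another changed gene within 25 identifiers, where 4.33 were expected (permutation p = 0.120). Their share was 35.0%, against 52.4% of the other 267 changed genes, which the hypothesis would not predict. The difference was not past the threshold (Fisher's exact test, two-sided p = 0.166). Changed genes near each other count each other, so they are not independent units and this p cannot weigh the hypothesis.

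Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 287 changed genes and the highest of the others 3, and only 1 split, the real one, reached 287. Every other split mixes mutant and wild type libraries, which widens the spread within its groups where the genotypes differ. The contrast was smaller for genes with an unadjusted limma p under 0.05. The real split had 3933, and the split placing mutant replicate 2 with wild type replicates 1 and 2 had 2131. For all-or-none genes the real split gave 20 and the highest other 3. With 10 splits no share under 0.05 can be reached.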
